A study of Caenorhabditis elegans with 6 samples.

How the data were processed

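RNA was measured in dopamine neurons and serotonin neurons of wild-type worms taken as embryos and larvae, with 3 libraries per cell type and each library in a column of its own. Per the labels, RNA was isolated with a PicoPure kit and libraries were made with an Ovation RNA-seq system from a nanogram scale of total RNA, which this kit amplifies before sequencing. How the cells were marked and collected, and whether replicates of the same number were handled together, is not given in the sources used here. The submitters' processing notes name STAR, HTSeq and DESeq2 without their roles, and versions, parameters, the genome build and the library strandedness are not given in the sources used here. Amplification of so little RNA raises the spread between libraries beyond counting error, and reads that match near-identical genes or genes overlapping on opposite strands may be lost or counted for the wrong gene.

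The deposited tables hold 47063 genes in 6 columns. The authors deposited a signal of normalized counts, which are read counts divided by 1 size factor per library. Each column had a single step of which the values were whole multiples within a tolerance of 0.02, apart from 1 value in dopamine 2, 1 in dopamine 3, 3 in serotonin 2 and 3 in serotonin 3. Division by the step and rounding gave reads per gene, and size factors estimated again from these reads differed from the deposited ones by at most 2.53% after a common factor. The value of 1 read ranged from 0.393 in serotonin 1 to 1.23 in serotonin 3, so differences of a few normalized counts have no precision. The authors also deposited FPKM values, for which the ratio to the normalized count was the same in all 6 columns of a gene (largest CV 0.0010 over 1624 genes with high counts in all libraries). The FPKM values therefore carry the same normalization between libraries and add the gene length. As an alternative they were taken as log2(FPKM + 1), where the added 1 shrinks differences of genes with low FPKM. Gene lengths implied by that ratio lay within 10% of the annotated exon union for 73.1% of 4194 protein-coding genes, so FPKM ranks between genes are approximate. Recovered reads per library ranged from 20418663 to 31559049. Between libraries of a group the chi-square per degree of freedom of recovered reads was 131 to 536, where a split of the same library would give about 1.

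Genes were matched by gene identifier to the WBcel235 assembly with Ensembl release 115 annotation, which covered 46407 of them and left 656 unmatched, and coordinates are those of this release. Values were taken as log2(normalized count + 1), and genes with at least 10 in at least 3 of the 6 libraries were tested, 15750 in all and 13156 of them protein-coding. Dopamine was compared with serotonin by limma 3.58.1 with the trend and robust options in R 4.3.3, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The choice of a log-scale linear model was fixed before the files were seen, for normalized counts, and it matched the unit found. Gene lists were tested by camera with a preset correlation of 0.01 for lists with at least 5 tested members, and again with an estimated correlation and by fry. Lists of channel families, peptides, receptors, cilia, pan-neuronal genes and markers of other cell types were fixed before the files were seen. The mitochondrial list was matched by annotation, as protein-coding genes of the mitochondrial genome, after the files were seen, because its symbols did not match. The named genes were the 10 with the largest fold change in each direction among genes past the threshold whose libraries did not overlap between groups and whose mean in the higher group was at least 50, all members of the identity and study lists, and up to 4 per other list with the largest fold change among those that passed, or the 2 with the highest mean where none did. Genes named outside this rule are marked in the text as chosen after their values were seen.

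Pairing of libraries by replicate number was checked on the data. Deviations from the group mean correlated at 0.433, 0.173 and 0.28 for dopamine and serotonin libraries of the same number, above those of the other pairs, so a fit with replicate number as a block is given beside results it changes. The labels give the number only as a name, and the main test was kept without the block as fixed before. The 2 libraries with the most ribosomal RNA, dopamine 1 and serotonin 3, were treated as a batch in added settings. Alternatives fixed before were other pseudocounts (0.5 and 8), no filter, a filter of 50, quantile and TMM scaling, FPKM, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the block, array weights, leaving out each library, and an adjusted p under 0.10. Added after the data were seen were the fit without the 2 ribosomal RNA-rich libraries, that batch as a covariate, scaling to pan-neuronal genes, scaling to ribosomal protein genes, and edgeR with the block. Scaling to pan-neuronal genes lowers the log2 fold change of every gene by the same 0.82, the mean of that list. A list median below this value therefore turns negative under it, whatever the list. Camera compares a list with all other genes, so a negative median there does not by itself reverse a camera call. Enrichment on the X chromosome was tested by Fisher's exact test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and statmod 1.5.0 in R, were also used.

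The method was tested on simulated negative binomial counts with the dispersions of these libraries and 14640 genes past the filter. Of planted changes, limma recovered 0% at 2-fold, 31.9% at 4-fold, 78.3% at 8-fold and 78.7% at 16-fold, with 8 calls among 14455 unchanged genes. The simulated libraries were not paired, and these values stand only for the fit without the replicate block. A gene that did not pass may thus differ by several fold. Of 2 planted lists of 20 genes, camera called the list shifted by 2-fold and did not call the unshifted one. The simulated genes were drawn independently of one another. Real list members were correlated, at an estimated 0.64 in both the pan-neuronal and the ciliary list, so the simulation does not test the preset of 0.01 on such lists. With 3 libraries per group an exact permutation test cannot give a p below 0.1, so no such test was used for single genes. Of 134 named genes, 7 share at least 10% of their exonic bases with another gene (ceh-22, dpy-10, mlc-2, sqt-3, tbh-1, pcbd-1 and dlc-5), and the counts of cha-1 and unc-17, which share a locus, are uncertain too. Every value column was used.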

Results

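Gene expression was measured by RNA-seq in 6 libraries from wild-type Caenorhabditis elegans, of which 3 were labelled as dopamine neurons and 3 as serotonin neurons. The labels give embryos and larvae as the source material and the same strain for all 6 libraries. In this nematode the dopamine neurons are ciliated mechanosensory cells that sense the texture of food, and the main serotonin neurons are the NSM cells of the pharynx and the chemosensory ADF cells. Nothing in the labels says that the replicates came from separate cultures or sorts, so the p-values measure only the spread between these libraries, which may be technical. Recovered reads assigned to genes came to 20418663, 27208221 and 27823600 in dopamine libraries 1, 2 and 3. The serotonin libraries 1, 2 and 3 held 31068770, 31559049 and 20457040. Nuclear ribosomal RNA genes took 40.9% of the reads in dopamine 1 and 41.5% in serotonin 3, against 7.53% to 13.7% in the other 4 libraries. Protein-coding genes held 10507502 to 25677630 reads per library. All levels below are deposited normalized counts, given as mean ± SD over 3 libraries, and log2 fold changes are dopamine minus serotonin on the scale of log2(normalized count + 1), from which folds were computed.

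The comparison of the cell types asked which transcripts, ion channels among them, set the mechanosensory dopamine neurons apart from the serotonin neurons. The dopamine transporter gene dat-1 was 187-fold higher in dopamine neurons, at 15924 ± 6331 against 81.7 ± 19 normalized counts (log2 fold change 7.55, SE 0.32, limma adjusted p = 2.02e-07). The tyrosine hydroxylase gene cat-2 was 58.3-fold higher there, and the homeobox gene ceh-43 and the ETS factor gene ast-1 were 17.5-fold and 6.66-fold higher. In the opposite direction, the tryptophan hydroxylase gene tph-1 was 110.2-fold higher in serotonin neurons, at 4492 ± 1224 against 65.1 ± 79.9 normalized counts (log2 fold change -6.78, SE 0.67, limma adjusted p = 7.17e-05). Dopamine 1 held 157 normalized counts of tph-1, against 18 and 19.9 in dopamine 2 and 3, and without it the tph-1 log2 fold change was -7.78. The serotonin reuptake transporter gene mod-5 was 42.7-fold higher in the serotonin libraries, at 2042 ± 223 against 48.9 ± 17.8.

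All 6 genes of the dopamine identity list passed the test in the dopamine direction, including the receptor gene dop-2 (log2 fold change 3.07) and the mechanosensory TRP channel gene trp-4 (2.21), and the list as a whole was higher in dopamine neurons (camera adjusted p = 5.15e-12, and adjusted p = 0.202 with an estimated correlation). The dop-2 call was lost among the 4 libraries with less ribosomal RNA (limma adjusted p = 0.0818, range over the alternatives 1.53e-04 to 0.0818). Of the 5 tested members of the serotonin identity list, 3 were higher in serotonin neurons (camera adjusted p = 9.76e-04, and adjusted p = 0.222 with an estimated correlation). The LIM homeobox gene ttx-3 was close to the threshold (log2 fold change -1.75, limma adjusted p = 0.0475). Its call was lost without dopamine 1, dopamine 3, serotonin 2 or serotonin 3 (limma adjusted p = 0.116, 0.112, 0.0978 and 0.18, range over the alternatives 0.00485 to 0.256). The POU homeobox gene unc-86 was at 481 ± 107 in dopamine and 544 ± 80.4 in serotonin libraries and did not pass, and neither did lim-4 (log2 fold change -0.33). The chemoreceptor gene srh-142 fell below the count filter and was not tested. Counts over each list alone were the same 6 and 3.

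Genes that both cell types need for monoamine synthesis and packaging were higher in dopamine neurons for 4 of 6 members, or 5 when adjusted over the list alone (camera adjusted p = 6.27e-06, and adjusted p = 0.258 with an estimated correlation). Scaling to pan-neuronal genes moved the median of this list from 1.38 to 0.56. The decarboxylase gene bas-1 was 3.35-fold higher and the dihydropteridine reductase gene qdpr-1, which acts in cofactor recycling, 8.28-fold higher. The vesicular monoamine transporter gene cat-1 (2.64-fold) and the GTP cyclohydrolase gene cat-4 (2.5-fold) lay nearer the threshold (limma adjusted p = 0.0199 and 0.0301). For each gene every dopamine library lay above every serotonin library. Where leaving out 1 library cost the call, the log2 fold change was 1.13 to 1.38 for cat-1 and 1.08 to 1.29 for cat-4. With all libraries these were 1.40 and 1.32. For cat-1 the call was lost without dopamine 1, dopamine 3 or serotonin 2 (limma adjusted p = 0.0559, 0.102 and 0.0749, range over the alternatives 4.13e-05 to 0.112). For cat-4 it was lost without dopamine 1, dopamine 3, serotonin 2 or serotonin 3 (limma adjusted p = 0.0991, 0.11, 0.112 and 0.0912, range 1.27e-04 to 0.333). The pcbd-1 gene did not pass (log2 fold change 1.37, limma adjusted p = 0.0519), but did with the replicate number as a block (limma adjusted p = 0.00857, range 0.00857 to 0.255) and without serotonin 3 (0.04996). Part of its exonic sequence overlaps a gene on the other strand, so its count is uncertain. The ptps-1 gene stood at 83.2 ± 20 and 52.9 ± 13.9 normalized counts and did not pass. The shared monoamine count higher in dopamine neurons was 2 without dopamine 1 or 3 or serotonin 2.

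**Figure D1:**
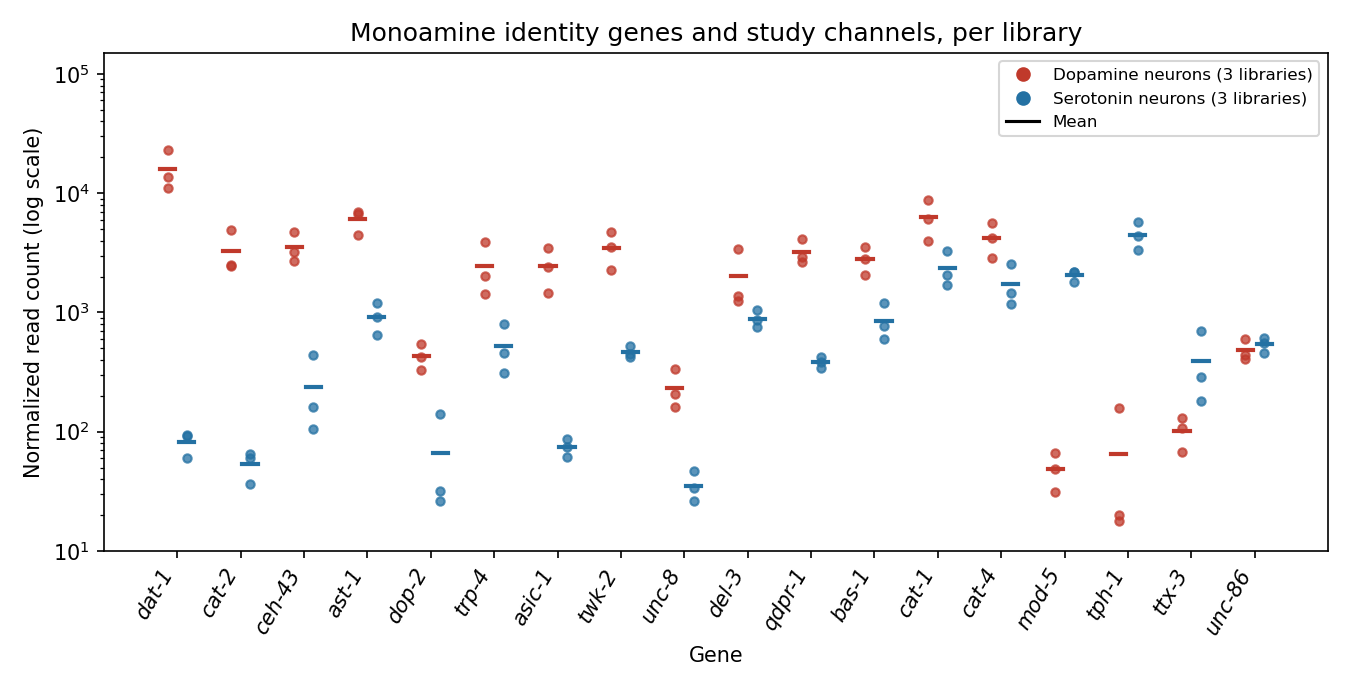
Normalized read counts (vertical axis, log scale) of monoamine identity genes and study channels (horizontal axis) in each library, with dopamine neurons in red, serotonin neurons in blue, and a bar at the mean of the 3 libraries. The dat-1 means are 15924 and 81.7 and the tph-1 means 65.1 and 4492 in dopamine and serotonin neurons, while unc-86 lies at a similar level in both.

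Among the ion channels linked to the study, the potassium channel gene twk-2 (WBGene00006657, chromosome II, 4441103 to 4453151) was 7.18-fold higher in dopamine neurons, at 3489 ± 1206 against 467 ± 52.8 normalized counts (log2 fold change 2.84, SE 0.30, limma adjusted p = 9.91e-05). The acid-sensing DEG/ENaC channel gene asic-1 (WBGene00022815, chromosome I, 3769672 to 3774005) was 31-fold higher, at 2446 ± 1021 against 74 ± 13.1. The degenerin gene unc-8 was 6.34-fold higher at a lower level, 234 ± 89.1 against 35.4 ± 10.5. It missed the threshold on the FPKM scale (limma adjusted p = 0.0519, range over the alternatives 1.44e-07 to 0.0519). Its serotonin mean of 0.64 FPKM lay below the 1 added on that scale. The study channel trp-4 (WBGene00006616, chromosome I, 13899085 to 13914008) was 4.62-fold higher. The DEG/ENaC gene del-3 stood at 2007 ± 1208 against 885 ± 149.6 and did not pass (log2 fold change 1.04, limma adjusted p = 0.108), but did with the replicate block (adjusted p = 0.0174, range 0.0174 to 0.646). By edgeR with the block del-3 did not pass. So 4 of the 5 study channels were higher in dopamine neurons, or 5 when adjusted over the list alone (camera adjusted p = 1.44e-07, and adjusted p = 0.258 with an estimated correlation). The study chose these channels on the same libraries, so neither the list test nor the count over the list alone is independent evidence.

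Channel families split between the cell types. Of 36 tested K2P potassium channel genes, 5 were higher in dopamine neurons, among them twk-3 (log2 fold change 4.53) and twk-17 (3.09), and 2 in serotonin neurons, twk-11 (-6.62) and twk-14 (-3.0). The K2P median was 0.05, or -0.77 when libraries were scaled to pan-neuronal genes and -0.09 when scaled to ribosomal protein genes. The K2P list did not pass (camera adjusted p = 0.0632), but did without dopamine 2 or serotonin 1 (camera adjusted p = 0.0274 and 0.0231, range over the alternatives 0.00175 to 0.422). For the 26 DEG/ENaC genes, asic-1 and unc-8 were higher in dopamine and egas-4 and asic-2 in serotonin neurons. The list did not pass (camera adjusted p = 0.857, with the camera direction opposite to the median). Its median was -0.35, or 0.01 after quantile normalization and -1.17 when scaled to pan-neuronal genes. The egas-4 call was lost without serotonin 1 or serotonin 2 (limma adjusted p = 0.057 and 0.0842, range 7.65e-06 to 0.103), and that of asic-2 without dopamine 1, 2 or 3 or serotonin 1 or 2 (adjusted p = 0.0539, 0.0545, 0.105, 0.12 and 0.197, range 0.00227 to 0.197). Among 18 TRP channel genes, trp-4 was higher in dopamine neurons, and the TRPV genes ocr-2 (-3.05) and ocr-3 (-2.18) and the gene trpl-5 in serotonin neurons (list median -0.43, camera adjusted p = 0.0732). Without dopamine 1 or serotonin 3 the TRP list passed (camera adjusted p = 0.0446 and 0.0493), and also without both (0.0329, range over the alternatives 0.0329 to 0.392). The trpl-5 call was lost without dopamine 3 or serotonin 3 (limma adjusted p = 0.0645 and 0.106, range 0.00146 to 0.36). TRP counts adjusted over the list alone were 1 and 5, and those of the K2P and DEG/ENaC lists did not differ from the counts over all genes. The DEG/ENaC count higher in serotonin neurons was 1 without dopamine 1 or 2 or 3 and 0 without serotonin 1 or 2. The TRP channel count higher in serotonin neurons was 5 without dopamine 1.

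As a list, voltage-gated calcium and NALCN channel genes were higher in dopamine neurons (camera adjusted p = 0.00451, and adjusted p = 0.301 with an estimated correlation), and its median of 0.99 became 0.17 when scaled to pan-neuronal genes. The T-type calcium channel gene cca-1 was 8.82-fold higher, at 14524 ± 3557 against 1616 ± 190 normalized counts, and the NALCN complex genes unc-80 and unc-79 were 3.39-fold and 3.16-fold higher. These 3 of 11 tested members passed, with 6 higher in dopamine and 1 in serotonin neurons when adjusted over the list alone. Voltage- and calcium-gated potassium channel genes went both ways, with 4 of 25 higher in dopamine neurons, such as shw-1 (log2 fold change 2.90), and 10 in serotonin neurons, such as kcnl-1 (-3.0). Their median was -0.53 (camera adjusted p = 0.425), and the counts over the list alone were 5 and 10. Of the other mechanosensory channel genes, none of 3 passed (median 0.21, or -0.61 when scaled to pan-neuronal genes). The pezo-1 gene stood at 742 ± 116 against 1442 ± 640.4 (limma adjusted p = 0.168) and passed toward serotonin neurons with the replicate block (adjusted p = 0.0222, range 0.0222 to 0.501) and without serotonin 3 (0.0282). It did not pass by edgeR with the block. The tmc-1 gene stood at 610.0 ± 247 against 513 ± 155 normalized counts. Of 16 stomatin-like and touch-complex genes, 3 were higher in dopamine neurons, including sto-4 (1.64), and 1 in serotonin neurons, sto-3 (-1.92), a call lost without serotonin 3 (limma adjusted p = 0.0521, range 7.88e-05 to 0.0521). That list did not move as a whole (median 0.12, or -0.70 when scaled to pan-neuronal and -0.02 to ribosomal protein genes, mean -0.26, camera adjusted p = 0.794), with 3 higher in dopamine and 3 in serotonin neurons when adjusted over the list alone. The stomatin-like and touch-complex count higher in dopamine neurons was 1 without dopamine 1 or 3 or serotonin 1 or 2, and that higher in serotonin neurons was 2 without dopamine 1, 3 without dopamine 2 and 0 without serotonin 3. The calcium and NALCN channel count higher in dopamine neurons was 5 without serotonin 3, and that higher in serotonin neurons was 1 without serotonin 1. The gated potassium channel count higher in serotonin neurons was 6 without dopamine 3, 4 without serotonin 1, 5 without serotonin 2 and 3 without serotonin 3.

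Within the dopamine neurons alone, 134 channel genes of these families were ranked by mean FPKM. The NALCN gene nca-1 was on the fixed list but was not found by its symbol, so it was neither tested nor ranked. The calcium channel gene cca-1 came first at 102.5 ± 25.1 FPKM (SD, n = 3), followed by the NALCN folding factor gene nlf-1 at 90.4 ± 24.2, the BK-type potassium channel gene slo-1 at 75.5 ± 25.8 and the calcium channel gene unc-2 at 68.8 ± 19.8. The genes nlf-1, slo-1 and unc-2 were named after their values were seen. Of the study channels, del-3 ranked 7 (61.3 ± 36.9 FPKM), asic-1 10 (44.2 ± 18.5), twk-2 14 (30.6 ± 10.6), trp-4 21 (18.4 ± 9.67) and unc-8 49 (4.2 ± 1.6). In serotonin neurons asic-1 averaged 1.34 FPKM and ranked 79, and del-3 averaged 27 and ranked 9. By mean normalized count, which takes no account of gene length, del-3 ranked 18, asic-1 14, twk-2 8, trp-4 13 and unc-8 51. A mean of at least 10 FPKM was reached by 36 of the 134 genes in dopamine neurons. Neighbouring ranks often differed by less than the SD between libraries, and no test was made of the ranks.

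Neuropeptide genes included the largest difference in the data. The FMRFamide-like peptide gene flp-33 (WBGene00011586, chromosome I, 12624234 to 12625238) was 404-fold higher in dopamine neurons, at 44484 ± 8761 against 116 ± 57.9 normalized counts (log2 fold change 8.66, SE 0.33, limma adjusted p = 1.88e-07). Of 30 tested genes of this class, 8 were higher in dopamine neurons, flp-5 (log2 fold change 4.67) and flp-4 (4.67) among them, and only flp-27 (-4.45) was higher in serotonin neurons (camera adjusted p = 9.50e-08, and adjusted p = 0.258 with an estimated correlation). Over the list alone the counts were 11 and 1, and the list median of 1.0 became 0.18 when scaled to pan-neuronal genes. Other neuropeptide genes were higher in dopamine neurons for 9 of 54, such as nlp-16 (3.40) and nlp-53 (2.83), while nlp-3 was 8.63-fold higher in serotonin neurons, with 10 higher in dopamine and 3 in serotonin neurons when adjusted over the list alone. Their list passed toward dopamine neurons (camera adjusted p = 0.00136, and adjusted p = 0.481 with an estimated correlation), but not without dopamine 2 (median 0.31, camera adjusted p = 0.0638, range over the alternatives 8.18e-07 to 0.481), and its median of 0.41 became -0.41 when scaled to pan-neuronal genes. Among 17 insulin-like peptide genes only daf-28 passed, 32.1-fold higher in serotonin neurons at 5135 ± 2431 against 155 ± 51.9 (list camera adjusted p = 0.168, 4 higher in serotonin neurons when adjusted over the list alone). The insulin-like list passed toward serotonin neurons among the 4 libraries with less ribosomal RNA (median -1.70 against -0.65, camera adjusted p = 0.0313, range over the alternatives 0.0313 to 0.861). After quantile normalization, where it did not pass, the insulin-like median was -0.06. The FMRFamide-like peptide count higher in serotonin neurons was 2 without dopamine 2. The other neuropeptide count higher in dopamine neurons was 5 without dopamine 2 or 3 or serotonin 1 or 3, and that higher in serotonin neurons was 2 without dopamine 1 and 3 without dopamine 2. The insulin-like peptide count higher in serotonin neurons was 2 without dopamine 1 and 3 without dopamine 2.

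Genes for peptide processing and dense-core vesicles were higher in dopamine neurons for 3 of 10 members, or 5 when adjusted over the list alone, and in serotonin neurons for 1, bli-4, in either case (camera adjusted p = 9.54e-04, and adjusted p = 0.301 with an estimated correlation). The list median of 0.74 became -0.08 when scaled to pan-neuronal genes. The proprotein convertase gene aex-5 was 5.11-fold higher, and the chaperone gene sbt-1 2.1-fold, a call lost without serotonin 2 (limma adjusted p = 0.0511, range 4.20e-04 to 0.431). The convertase gene bli-4 (log2 fold change -1.01) lost its call without dopamine 1, 2 or 3 or serotonin 2 or 3 (limma adjusted p = 0.0535, 0.114, 0.116, 0.161 and 0.0858, range 0.00445 to 0.161). The peptide processing count higher in dopamine neurons was 1 without serotonin 2, and that higher in serotonin neurons was 0 without dopamine 1 or 2 or 3 or serotonin 2 or 3. Pan-neuronal genes, which serve synaptic transmission in all neurons, were higher in dopamine neurons for 9 of 18 members, or 13 over the list alone, with a median log2 fold change of 0.86 (camera adjusted p = 7.66e-08, and adjusted p = 0.392 with an estimated correlation). Examples were the syntaxin gene unc-64 (1.28) and the gene rgef-1 (1.34). The unc-64 call was lost without dopamine 3 (limma adjusted p = 0.0553, range 2.64e-04 to 0.175), and the rgef-1 call without dopamine 3 or serotonin 2 (adjusted p = 0.0789 and 0.0607, range 2.32e-04 to 0.15). The pan-neuronal count higher in dopamine neurons was 3 without dopamine 1, 0 without dopamine 3, 4 without serotonin 1 and 1 without serotonin 2. By camera the pan-neuronal list itself passed with each library left out, but by fry with all libraries it did not (adjusted p = 0.0766). The same dopamine libraries held 169 normalized counts of the pharyngeal muscle gene myo-2 on average and the serotonin libraries 17819.

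Monoamine receptor genes were higher in dopamine neurons for 6 of 20 members and higher in serotonin neurons for dop-5, with 9 higher in dopamine and 3 in serotonin neurons when adjusted over the list alone. The ligand-gated channel gene lgc-53 was 45-fold higher in dopamine neurons, at 1336 ± 171 against 32.6 ± 20.3, and the dopamine receptor gene dop-1 5.57-fold higher, a call lost without dopamine 3 (limma adjusted p = 0.0628, range 1.19e-04 to 0.0732). The dop-5 gene (log2 fold change -2.38) lost its call without dopamine 3 or serotonin 3 (limma adjusted p = 0.0517 and 0.0985, range 0.00541 to 0.0985). The list passed (camera adjusted p = 0.00988, and adjusted p = 0.301 with an estimated correlation), but not without dopamine 1 (median 0.73, camera adjusted p = 0.053) or among the 4 libraries with less ribosomal RNA (median 0.67, adjusted p = 0.0636, range over the alternatives 1.10e-05 to 0.301), and its median of 0.75 became -0.07 when scaled to pan-neuronal genes. Of 77 acetylcholine and other cys-loop receptor genes, 12 were higher in dopamine and 7 in serotonin neurons, the latter led by acr-25 (513 ± 61 against 5.15 ± 4.1) and acr-3 (191 ± 38.4 against 2.46 ± 3.28). Adjusted over the list alone these were 17 and 12. The list did not pass (camera adjusted p = 0.0982) but did without serotonin 1 (0.0231, range over the alternatives 0.00101 to 0.425), and its median of 0.19 differed in sign from its mean of -0.03 and became -0.63 when scaled to pan-neuronal genes. The monoamine receptor count higher in serotonin neurons was 2 without dopamine 1 and 0 without dopamine 3 or serotonin 3. The cys-loop receptor count higher in dopamine neurons was 6 without dopamine 3 or serotonin 3 and 7 without serotonin 2.

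Lists of sensory genes had more calls toward serotonin than dopamine neurons. The dynein heavy chain gene che-3, which drives transport in cilia, was 6.14-fold higher in serotonin neurons, at 11407 ± 2142 against 1870.3 ± 419, and the intraflagellar transport genes daf-10 and dyf-2 were 5.69-fold and 4.9-fold higher. Of 45 ciliary genes 11 were higher in serotonin neurons and 1, the tubulin gene tbb-4 (log2 fold change 1.74, named after its value was seen), in dopamine neurons, with 2 higher in dopamine and 16 in serotonin neurons when adjusted over the list alone. The list had a median of -0.67 (camera adjusted p = 1.09e-04, and adjusted p = 0.664 with an estimated correlation) but did not pass among the 4 libraries with less ribosomal RNA (median -0.23, camera adjusted p = 0.473, range over the alternatives 1.38e-10 to 0.664). Chemoreceptor genes were higher in serotonin neurons for 27 of 274 tested members and in dopamine neurons for 7, with 7 higher in dopamine and 31 in serotonin neurons when adjusted over the list alone (median -1.26, camera adjusted p = 1.53e-04, and adjusted p = 0.593 with an estimated correlation). The chemoreceptor call was lost when scaled to pan-neuronal genes (median -2.08, camera adjusted p = 0.426) and on DESeq2 values (median -1.06, adjusted p = 0.0542, range over the alternatives 1.29e-08 to 0.593). After quantile normalization it was kept, with a smaller median of -0.44. Over all 15750 tested genes, 1002 were higher in serotonin and 498 in dopamine neurons. At least 10 reads were held by 21788, 18802 and 14135 genes in serotonin 1, 2 and 3. In dopamine 1, 2 and 3 these were 16214, 15465 and 14912 genes. Whether the shift of these low-count chemoreceptor genes follows from the number of genes detected was not tested. In dopamine libraries the leading members had only a few reads, with str-79 at 116 ± 66.1 against 1.11 ± 0.0874 and srj-18 at 112 ± 10.5 against 1.77 ± 1.6 normalized counts, so no fold is given. In cyclic-nucleotide signalling 2 of 43 genes were higher in dopamine and 8 in serotonin neurons, with 3 higher in dopamine and 9 in serotonin neurons when adjusted over the list alone. They included the receptor guanylate cyclase genes gcy-15 (-5.49) and gcy-21 (-5.30, or -6.21 without dopamine 1 and -4.21 without dopamine 3) and the channel subunit gene tax-2 (-2.72). The list median was -0.04, or 0.03 after quantile normalization (camera adjusted p = 0.331). The gcy-11 gene passed (log2 fold change -5.17, or -6.13 and -4.04 without dopamine 1 or 3, limma adjusted p = 0.00262), but not with the replicate block (adjusted p = 0.155, range 1.50e-07 to 0.155) or without serotonin 1 (0.0733). By fry neither the ciliary nor the chemoreceptor list passed (adjusted p = 0.183 and 0.155). The ciliary count higher in dopamine neurons was 2 without serotonin 3, and that higher in serotonin neurons was 6 without dopamine 1 or 2 and 5 without serotonin 3. The chemoreceptor count higher in dopamine neurons was 3 without dopamine 1 or serotonin 2, 4 without dopamine 2 or serotonin 1 or 3 and 2 without dopamine 3, and that higher in serotonin neurons was 49 without dopamine 1, 16 without dopamine 3 and 11 without serotonin 1 or 2 or 3. The cyclic-nucleotide signalling count higher in dopamine neurons was 0 without dopamine 3 or serotonin 2 and 1 without serotonin 1. The same serotonin libraries held more RNA of pharyngeal muscle markers, with a median log2 fold change of -6.32.

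Markers of pharyngeal muscle had the largest median change of all lists. All 6 were higher in the serotonin libraries, with a median log2 fold change of -6.32 (camera adjusted p = 8.26e-13, and adjusted p = 0.222 with an estimated correlation) and the same count when adjusted over the list alone. The myosin heavy chain gene myo-2 stood at 17819 ± 8873 against 169 ± 55.4 normalized counts, myo-1 at 11106 ± 3514 against 129 ± 10.7, the troponin I gene tni-4 at 8881 ± 2611 against 91.4 ± 52.1, and the homeobox gene ceh-22 at 733 ± 181 against 30.2 ± 18.4. Genes listed as body-wall muscle markers moved apart from one another. Of 11, 5 were higher in serotonin libraries, led by the myosin light chain gene mlc-1 (-4.57) and the tropomyosin gene lev-11 (-3.50), and 1 in dopamine libraries, with the same counts over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.392 with an estimated correlation). The mlc-1 and mlc-2 genes are near-identical copies, so their counts are uncertain. Whether transcripts of the 5 genes came from body-wall or from pharyngeal muscle cannot be told from these counts. The gene higher in dopamine libraries was the body-wall myosin gene unc-54 (1.17), at 32487 ± 12180.5 in dopamine against 14123 ± 3573 in serotonin libraries, whereas its partner myo-3 stood at 716 ± 542 against 709.6 ± 202, and both were named after their values were seen. Counts per gene do not show whether unc-54 reads came from the gene itself or from a reporter transgene carrying unc-54 sequence, and the labels name no transgene. The body-wall muscle count higher in dopamine neurons was 0 without dopamine 3 or serotonin 2, and by fry the body-wall list did not pass (adjusted p = 0.0551). No pharyngeal gland marker of 7 passed, and the list did (median -1.45, camera adjusted p = 0.0411, and adjusted p = 0.392 with an estimated correlation), but not without dopamine 1, dopamine 3 or serotonin 2 (medians -1.23, -1.19 and -1.11, camera adjusted p = 0.182, 0.0724 and 0.157, range over the alternatives 0.0038 to 0.392). Its member phat-5 (log2 fold change -1.97) passed with the replicate block (limma adjusted p = 0.0411, range 0.00561 to 0.869) and without dopamine 2 (0.00561). Under edgeR with the block phat-5 did not pass.

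Markers of single neuron classes gave a mixed picture. Of 6 ADF-associated genes 3 were higher in serotonin libraries, namely tph-1 and the G protein genes gpa-13 (-4.22) and gpa-10 (-4.18), with the same count over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.222 with an estimated correlation). That list, with a median of -2.47, did not pass among the 4 libraries with less ribosomal RNA (median -1.64, camera adjusted p = 0.0731, range over the alternatives 1.01e-06 to 0.222). NSM-associated genes went both ways, with tph-1, nlp-3 and ttx-3 higher in serotonin and flp-4 and nlp-18 higher in dopamine libraries of 9 tested, and the same counts over the list alone (median -0.19, camera adjusted p = 0.854). Touch receptor markers were higher in dopamine libraries for mec-7 and mec-12 of 7, or 3 over the list alone (camera adjusted p = 0.00643, and adjusted p = 0.392 with an estimated correlation), and the list median of 1.11 became 0.29 when scaled to pan-neuronal genes. Both calls were lost without dopamine 2, dopamine 3 or serotonin 1, with limma adjusted p = 0.0614, 0.0576 and 0.0625 for mec-7 (range 9.62e-04 to 0.198) and 0.0627, 0.0873 and 0.0788 for mec-12 (range 0.00108 to 0.324). Lists with under 5 tested members had no set test. None of the GABA neuron genes (4 tested, median 1.19), cholinergic genes (4, -0.78), tyramine and octopamine genes (2, 1.78), glial genes (4, -0.87) or coelomocyte genes (3, 0.39, or -0.43 when scaled to pan-neuronal genes) passed over all genes. Adjusted over the list alone, 1 GABA gene, unc-25, and both tyramine and octopamine genes, tdc-1 and tbh-1, were higher in dopamine libraries. With the replicate block unc-25 and tdc-1 passed (limma adjusted p = 0.0232 and 0.0195, ranges 0.016 to 0.326 and 0.00742 to 0.342), and tdc-1 without dopamine 1 (0.0361). The touch receptor count higher in dopamine neurons was 0 without dopamine 2 or 3 or serotonin 1. That list did not pass by fry (adjusted p = 0.0992).

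Of 90 homeobox genes, 6 were higher in dopamine neurons, led by ceh-43, and 10 in serotonin neurons, such as ceh-22, itself a marker of pharyngeal muscle, and ceh-54 (115 ± 37.3 against 5.79 ± 8.53 normalized counts), with 6 higher in dopamine and 12 in serotonin neurons when adjusted over the list alone. The homeobox list did not pass (median -0.18, or 0.16 after quantile normalization, camera adjusted p = 0.854, with the camera direction opposite to the median). Gap junction innexin genes split, with unc-9 5.71-fold higher in dopamine neurons at 6985 ± 2077 against 1220.1 ± 352, and inx-6 (-4.21), itself expressed in pharyngeal muscle, inx-3 (-2.13) and che-7 (-2.32) higher in serotonin neurons. Over all genes 2 and 3 of 23 innexins passed, over the list alone 3 and 3 (camera adjusted p = 0.70). No member of the intestine, hypodermis and germline lists passed, and neither did the lists, with medians of -1.14, 0.56 and -0.58 (camera adjusted p = 0.407, 0.857 and 0.726). The hypodermis median became -0.26 when scaled to pan-neuronal genes and differed in sign from the mean of -0.28. Adjusted over the list alone, 1 intestine gene, spl-1, was higher in serotonin libraries, and it passed over all genes with the replicate block (limma adjusted p = 0.0223, range 0.020 to 0.253) and without dopamine 2 (0.0291). With edgeR and the block spl-1 did not pass. None of 79 ribosomal protein genes passed, while their list did (median 0.13, camera adjusted p = 0.0105, and adjusted p = 0.749 with an estimated correlation), but not without dopamine 2, dopamine 3 or serotonin 3 (camera adjusted p = 0.123, 0.0777 and 0.217, range over the alternatives 1.36e-04 to 0.749), and its median became -0.69 when scaled to pan-neuronal genes. Heat-shock genes (median -0.79, camera adjusted p = 0.10) and mitochondrially encoded genes (median -0.13, camera adjusted p = 0.854) did not pass, with no member past the threshold. The heat-shock list passed toward serotonin neurons with the replicate block (camera adjusted p = 0.00501) and without dopamine 2 or serotonin 1 (5.18e-04 and 0.017, range over the alternatives 5.18e-04 to 0.749). The heat-shock gene dnj-13 (log2 fold change -0.78) passed with the replicate block (limma adjusted p = 0.00246, range 0.00246 to 0.648). The homeobox count higher in serotonin neurons was 6 without serotonin 3. The innexin count higher in dopamine neurons was 1 without dopamine 1 or 2 or 3 or serotonin 1 or 2. The heat-shock count higher in serotonin neurons was 2 without dopamine 2. The mitochondrially encoded count higher in serotonin neurons was 1 without serotonin 3.

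**Figure D2:**
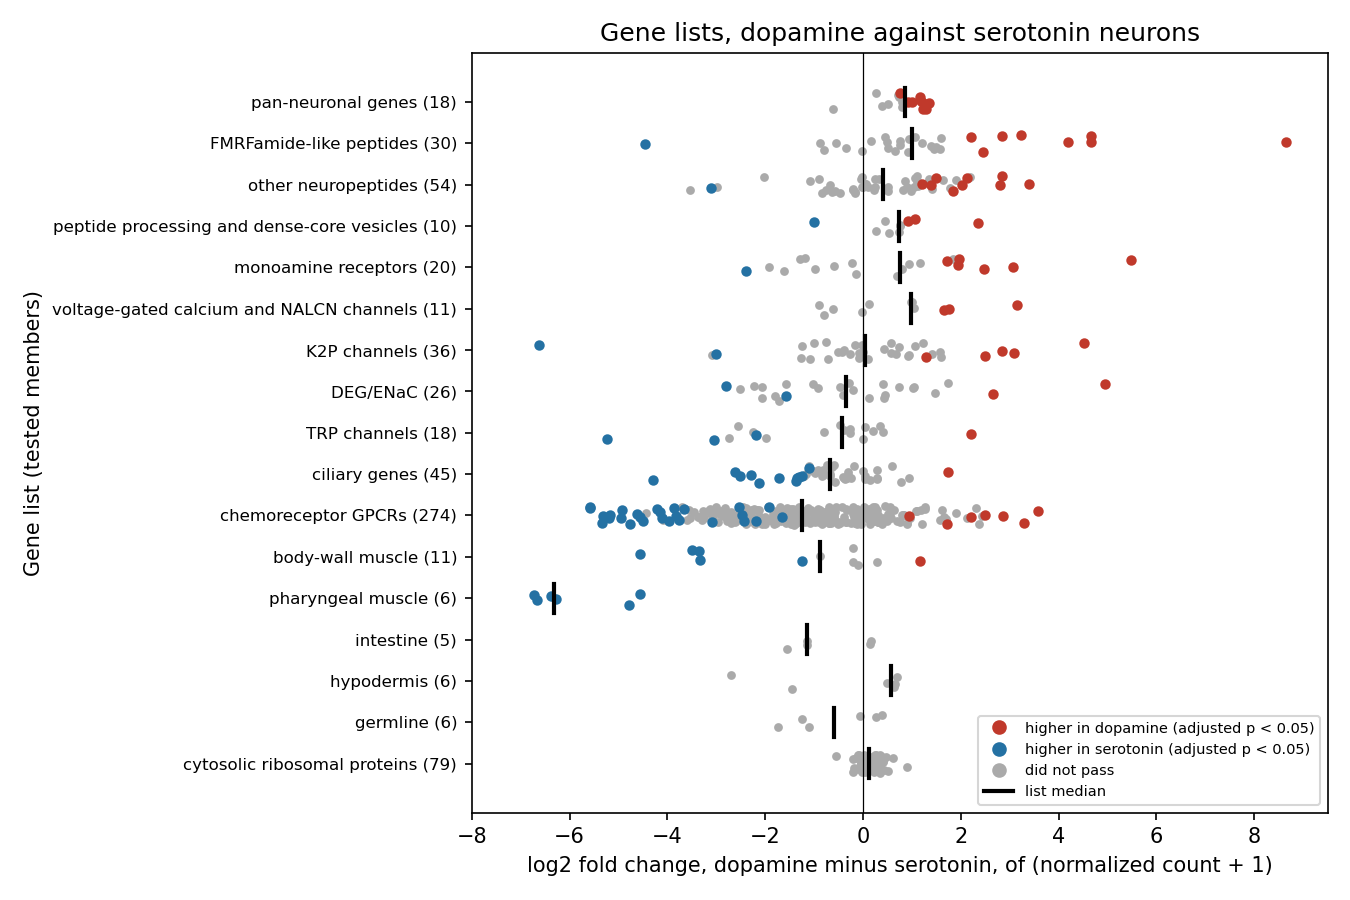
Log2 fold change, dopamine minus serotonin (horizontal axis), of the tested members of selected gene lists (vertical axis, number tested in parentheses), with members past the threshold in red or blue, others in grey, and a black bar at each median. Pharyngeal muscle lies lowest at -6.32, the DEG/ENaC median turns positive after quantile normalization, and the medians of the other neuropeptide, peptide processing, monoamine receptor, K2P, hypodermis and ribosomal protein lists turn negative when scaled to pan-neuronal genes. That scaling lowers the log2 fold change of every gene by the same 0.82.

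Over all 15750 tested genes, 498 were higher in dopamine and 1002 in serotonin neurons (limma, Benjamini-Hochberg adjusted p under 0.05), of which 218 and 753 differed by at least 4-fold. In 27.4% of tested genes the 3 libraries of each cell type did not overlap, where chance gives 10%. Besides flp-33 and dat-1, the 10 largest differences toward dopamine neurons were the alpha-tubulin gene tba-9 (log2 fold change 8.43), F59F3.6 (7.70), F58H7.1 (7.06), F09E10.7 (6.75), twnk-1 (6.55), R11G1.1 (6.47), arrd-23 (6.21) and the non-coding gene T23G5.11 (6.0). The R11G1.1 gene reached 61158 ± 26699 normalized counts in dopamine neurons against 662 ± 158. T23G5.11 (chromosome III, 9242530 to 9242726) is annotated on the opposite strand just upstream of dat-1 (chromosome III, 9242975 to 9246802). Toward serotonin neurons, the 10 largest were tph-1, tni-4, myo-2, twk-11 (23046 ± 7570 against 234.9 ± 80.8), acr-25, C09B8.3 (-6.55, or -7.35 to -5.04 with 1 dopamine library left out), the troponin T gene tnt-4 (-6.54), dlc-5 (553 ± 155 against 5.73 ± 3.79), Y70C5A.2 (328 ± 277 against 4.88 ± 7.53) and myo-1, so that 4 of them are contractile genes of the pharynx. For acr-25, dlc-5 and Y70C5A.2 the dopamine libraries held only a few reads, so no fold is given and their order is uncertain. The dlc-5 gene overlaps a non-coding gene on the other strand, and its count is uncertain.

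**Figure D3:**
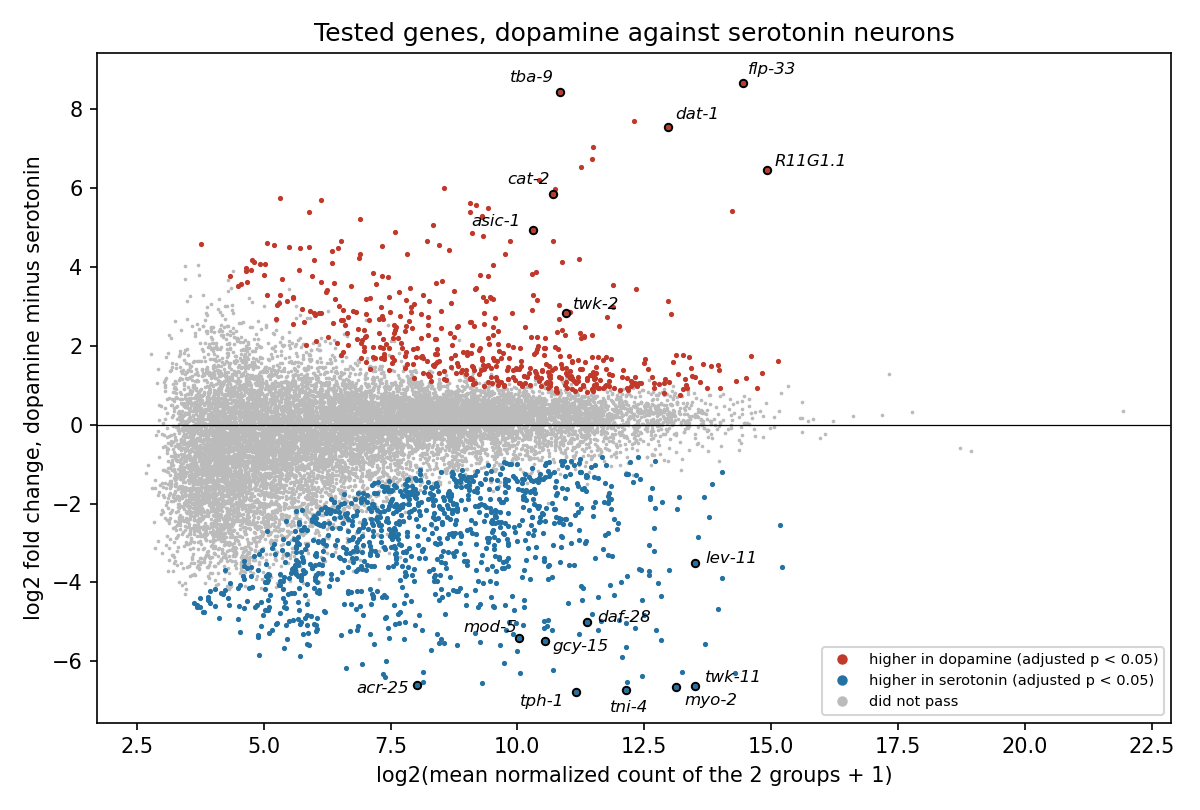
Log2 fold change, dopamine minus serotonin (vertical axis), against the log2 of the mean normalized count of both groups plus 1 (horizontal axis) for the 15750 tested genes, with 498 genes higher in dopamine neurons in red, 1002 higher in serotonin neurons in blue and the others in grey. Labelled genes span log2 fold changes from -6.78 for tph-1 to 8.66 for flp-33.

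With the replicate number as a block, 1068 genes were higher in dopamine and 1842 in serotonin neurons. Leaving out dopamine 3 gave 224 genes higher in dopamine neurons, leaving out serotonin 2 gave 316 and 637, and leaving out serotonin 3 gave 581 higher in serotonin neurons. Folds given above also moved by more than 1.5-fold for ceh-43 (log2 fold change 4.72 without serotonin 2), dop-2 (3.82 without serotonin 1), dop-5 (-1.66 without dopamine 3), gcy-15 (-4.70 without serotonin 3), inx-6 (-3.47 without dopamine 1), gpa-10 (-3.49 without dopamine 2) and lim-4 (-0.92 without dopamine 2). The phat-5 value moved both ways, to -3.48 without dopamine 2 and -2.61 without serotonin 1, and to -1.23 without dopamine 1 and -1.19 without dopamine 3. The 2 libraries rich in ribosomal RNA fell in different groups. Without them, 294 and 753 genes passed, and with that library property as a covariate 442 and 906, while the 2 libraries themselves, 1 per group, allow no test. Scaling to pan-neuronal genes moved the median log2 fold change of all genes from -0.07 to -0.89 and the share of calls toward dopamine neurons from 33.2% to 6.51%, with 173 and 2484 calls. Scaling to ribosomal protein genes gave a median of -0.21 and a share of 22.9%, and quantile normalization a median of 0.13. Correlations of log2 values across genes averaged 0.907 within and 0.837 between groups, and the first principal component held 51.1% of the variance. Dopamine 1 lay nearest to the serotonin libraries on it, and its correlation with serotonin 1 (0.886) exceeded that with dopamine 2 (0.881).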

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

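The fits without the 2 ribosomal RNA-rich libraries, with that batch as a covariate, with scaling to pan-neuronal or ribosomal protein genes, and edgeR with the replicate block were chosen after the results were seen. Counts of genes higher in dopamine and in serotonin neurons were 498 and 1002, and 1068 and 1842 with the replicate block, which changed no named gene or list other than those given in the report. They were 294 and 753 without the 2 rich libraries, 442 and 906 with the covariate, 173 and 2484 when scaled to pan-neuronal genes, 294 and 992 when scaled to ribosomal protein genes, and 778 and 1183 by edgeR with the block. Leaving out single libraries gave 224 to 455 and 581 to 1289. Pseudocounts of 0.5 and 8 gave 485 and 947, and 547 and 1158. The count was 442 and 959 with no filter, 522 and 909 with the stricter filter, 736 and 1021 after quantile normalization, 509 and 994 by TMM, 476 and 897 by FPKM, 385 and 729 by edgeR, 719 and 1497 by DESeq2, 537 and 1050 with array weights, and 726 and 1400 at an adjusted p under 0.10. Camera called 11 lists higher in dopamine and 7 in serotonin neurons, fry 7 and 3, and camera with an estimated correlation 0 and 0. Toward dopamine neurons fry did not call the pan-neuronal, other neuropeptide, touch receptor or ribosomal protein lists (adjusted p = 0.0766, 0.183, 0.0992 and 0.574). Toward serotonin neurons it did not call the ciliary, chemoreceptor, body-wall muscle or pharyngeal gland lists (fry adjusted p = 0.183, 0.155, 0.0551 and 0.122). When scaled to pan-neuronal genes, the medians of the called lists of other neuropeptides (-0.41), peptide processing (-0.08), monoamine receptors (-0.07) and ribosomal proteins (-0.69) turned negative. So did 2 called genes and medians of lists not called. Of the called lists just named, camera still called all toward dopamine neurons there except ribosomal proteins (adjusted p = 0.111). It also called the K2P (median -0.77) and cys-loop (-0.63) lists toward dopamine neurons (camera adjusted p = 0.00175 and 0.00101). The chemoreceptor and pharyngeal gland calls toward serotonin neurons were lost (camera adjusted p = 0.426 and 0.216). The gene rpl-3 passed toward serotonin neurons there (-0.72). Correlations within and between groups, 0.907 and 0.837, were 0.866 and 0.761 on FPKM and 0.928 and 0.901 without a filter. The cause of these changes was not tested, though fits with fewer libraries have less power. In the libraries with most ribosomal RNA, 1 read was worth up to 1.23 normalized counts, which limits genes with few reads. The median rank of the 5 study channels was 14 by FPKM and by normalized count, and 13 to 14 without single dopamine libraries. Of 134 named genes 31 did not pass, and 19 of these did in no alternative that gave a value. Of the others, 73 passed in every alternative that gave a value and 76 with each library left out.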

Other observations

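All tests here were written after the results were seen, except those of the X chromosome and the splits of libraries. Genes given as examples of a family were chosen after their values were seen. Gene families sharing a name of at least 10 tested members were tested for an excess of calls, 129 in all (Fisher's exact test, adjusted by Benjamini and Hochberg). Genes for the vacuolar proton pump were higher in dopamine neurons for 8 of 20 vha genes (adjusted p = 5.49e-06), such as vha-2 (log2 fold change 1.22) and vha-13 (1.34), with a family median of 0.86, or 0.04 when scaled to pan-neuronal genes. In serotonin neurons 9 of 18 tetraspanin genes were higher (adjusted p = 6.12e-05), led by tsp-4 (-5.22) and tsp-6 (-4.09). So were 8 of 16 sensory G protein alpha subunit genes (adjusted p = 1.37e-04), among them gpa-2 (-3.69) and gpa-3 (-2.75), 28 of 181 nuclear receptor genes of the nhr family (adjusted p = 7.36e-04) and 12 of 48 pqn genes (adjusted p = 0.00109). The flp, nlp, lgc and unc names also had an excess of calls toward dopamine neurons, and the medians of the latter 3 turned negative when scaled to pan-neuronal genes (-0.57, -0.50 and -0.41).

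Some single genes were picked after their values were seen. The gene lin-15B stood at 63162 ± 16295 normalized counts in serotonin against 10688 ± 1294 in dopamine libraries (log2 fold change -2.53), and its neighbour lin-15A differed likewise (-2.85). Counts per gene do not show whether these reads came from the genes themselves or from a transgene carrying lin-15 sequence, and the labels name no transgene. The channel subunit gene tax-4, partner of tax-2, was also higher in serotonin neurons (-2.68).

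Genes on the X chromosome were over-represented among calls in both directions. Of the 498 genes higher in dopamine neurons 27.3% lay on X, against 15.2% of tested genes (odds ratio 2.16, Fisher's exact p = 2.42e-12, and 2.26 with expression and length in the model). For serotonin neurons the share was 21.8% (odds ratio 1.6, Fisher's exact p = 1.53e-08, and 1.61 with those terms).

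A hypothesis for the pharyngeal muscle genes in the serotonin libraries is that pharyngeal muscle cells were collected with the serotonin neurons, some of which lie in the pharynx. A second list, of genes linked to the pharynx, held tnt-4 and inx-6, already seen to be higher. Its 8 other members had a median log2 fold change of -1.198 (SE over members 0.45), with 1 past the threshold, pha-4 (limma adjusted p = 0.0202). Such counts cannot tell expression in muscle from expression in pharyngeal neurons, so the hypothesis stays open. Scaling is an unlikely cause, since the median nearest 0 over the scalings was -6.28 while they put the median of all genes between -0.89 and 0.13. A general rise of non-neuronal cells is unlikely too, since the lowest median among the hypodermis, intestine, germline, glia and coelomocyte lists, that of intestine (-1.14), lay 5.18 log2 units above, and the pharyngeal gland list, not part of that comparison, had a median of -1.45. Expression by the serotonin neurons themselves stays open, as the ratio of these genes to tph-1 varied 2.19-fold between the 3 serotonin libraries.

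Pan-neuronal genes may be higher in dopamine libraries because these held a larger share of neuronal RNA. A difference between libraries in the distribution of values is an unlikely cause, since after quantile normalization the median was 0.819 (camera adjusted p = 1.24e-06, range over the alternatives 5.89e-13 to 0.392). A uniform dilution in the serotonin libraries predicts equal shifts of all members, and their spread was 1.72 times the standard error. Members correlated at an estimated 0.64, so the standard error of single genes does not measure the spread expected under equal shifts. That comparison therefore cannot decide on uniform dilution, which stays open.

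For the ciliary genes, chemosensory neurons of all amphid classes among the serotonin cells stay open as an explanation. The median over the amphid classes of their marker medians was 0.0974 with an SD of 2.0. Apart from the ASG class, the class medians lay between -0.99 (ASJ) and 0.90 (ASI), so no shift shared by all tested classes was seen. Only 8 of 11 classes had a tested marker, however, 5 of them a single gene. Of the 9 markers under the count filter, 8 had a higher mean in serotonin libraries, at 17.5 normalized counts or less. A difference in scaling of the kind that quantile normalization removes is an unlikely cause, as the ciliary median was -0.663 after it. Scaling to pan-neuronal or ribosomal protein genes lowers all log2 fold changes, so it could not bring that median nearer 0. Without the 2 ribosomal RNA-rich libraries the ciliary median was -0.23, and the cause of that change was not tested. Markers of the ASG class, gcy-15 and gcy-21, had a median of -5.40, but were seen to be higher in serotonin libraries before they were chosen.

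Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many genes past the threshold, with 1500, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 3524 genes and the others at most 1443. The 3 other splits that part all same-numbered pairs also gave 0. These 10 splits are too few for a share under 0.05.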
